A study of Drosophila melanogaster with 16 samples.

How the data were processed

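Total RNA of dissected wing discs and brain complexes was labelled as biotin cRNA and hybridised to single-colour Affymetrix Drosophila Genome 2.0 arrays, 16 in all, with 6 groups of tissue and genotype. The deposited values are log2 signals made by the authors with GCRMA, which corrects background, normalizes between arrays and summarises the probes of a probe set. The version of that method is not given. The values share a floor of 2.21 on every array. Arrays were grouped by tissue and genotype from the labels. No array was left out of the comparisons.

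The table held 18952 probe sets, of which 13647 carried 1 gene symbol, 402 several, 4720 none and 183 were controls. Gene names and chromosome arms came from the supplied annotation tables, the latter on assembly Release 6 plus ISO1 MT. No coordinates are given. Probe sets at or above 4 on the log2 scale on at least 2 arrays were tested, 8819 in all. For statements on genes, each of 7213 genes was represented by the probe set with the highest mean.

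Differences were tested with limma 3.58.1 in R 4.3.3, in a single model with a mean for each of the 6 groups and 10 residual degrees of freedom. The 9 contrasts were each mutant against wild type per tissue, lgl against scrib per tissue, wild-type disc against brain, and the difference of each mutant effect between tissues. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 within the contrast. Folds come from the group means. Where any array of the dimmer group lay below 4, that array was set to 4 and the fold is written as at least that large, a rule widened after the values were seen from groups with a mean below 4. No fold is given where both means lay below 4. The comparisons of each mutant with wild type share their wild-type arrays, so the overlap of their calls was set beside independent calls and 100 simulated draws with shared controls.

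The 27 gene lists cover JNK, Hippo, JAK/STAT, Notch and ecdysone pathways, cell polarity, basement membrane, DNA replication, mitosis, apoptosis, oxidative stress, heat shock, immune peptides, glycolysis, temporal identity and Hox genes. They also cover markers of wing disc, neurons, neuroblasts, glia, eye, ring gland, fat body, hemocytes, muscle, salivary gland and dosage compensation. The 25 lists with at least 5 measured genes were tested with camera in limma with a preset correlation of 0.01, adjusted over all lists and 6 contrasts. An alternative estimated the correlation between genes. Calls adjusted over a list alone are given where they differ in number. Differences of effects between tissues were adjusted over 25 lists and both mutants.

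The groups, lists, filter, model, thresholds, naming rule and most alternatives were fixed before the data were examined. By that rule l(2)gl and scrib are named in every group. Each contrast of a mutant with wild type names up to 6 rises and 6 falls that were the largest among called genes, with every mutant array on the same side of both wild-type arrays. Genes known only by a CG or CR number were passed over. They are ordered by log2 change, although values below 4 have no measured order. Each list names up to 4 members per contrast with the smallest adjusted p. The contrasts of lgl with scrib and of effects between tissues name the 4 largest differences each way, and 8 genes each way are named among those called in all 4 mutant groups.

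Alternatives were no filter, a filter at 6, a trended and robust variance, quantile normalization added, a replicate block, 1 probe set per gene, a fit on the arrays of the tissue or groups compared, a fold of at least 2 as well, and leaving out each array in turn. Chosen after seeing the data were array weights by group, leaving out the probe sets at least 4-fold higher in wild-type brain than disc, and leaving out both replicate 1 wild-type arrays. The genes drawn per array were chosen after their values were seen. Ranges of adjusted p beside a named gene or list are over its alternatives.

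Simulations of 8819 probe sets planted 100 changes of each size per contrast, at means of 6 or more. All groups had the same SD, unlike the data. Over 6 contrasts within a tissue the model recovered 47% to 68% of changes of 1 log2 and 89% to 98% of 2 log2. Of calls, 3.38% to 7.69% were false. In simulated lgl discs camera found 1 log2 planted in 19 JNK genes (adjusted p = 4.97e-25, 7.58e-05 with estimated correlation). It called 0 of 24 other lists. Correlated genes were not simulated.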

Results

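The data were 16 arrays of total RNA from dissected larvae of the third instar. Each array held RNA of wing discs or brain complexes. Wild-type larvae were taken at day 5 after egg deposition, with 2 arrays per tissue. Larvae mutant for l(2)gl (called lgl here, alleles lgl27S3/lglE2S31) or for scrib (alleles scrib1/scrib2) were taken at day 9, with 3 arrays per tissue and genotype. Both genes encode scaffold proteins of epithelial cell polarity. In every comparison of a mutant with wild type, genotype and age therefore changed together. Between 40.2% and 43.2% of the 18952 probe sets lay at or above a log2 value of 4 on each array. The number of arrays limits the precision. The pooled within-group SD was 0.65 log2 for wild-type discs and 0.66 for wild-type brains, against 0.33 to 0.45 in the 4 mutant groups. The p-values measure only the spread between samples of a group, which may be technical. Leaving out a wild-type array leaves 1 array, which is then assumed to vary like the other groups.

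Tissue markers followed the labels in wild type. All 20 measured wing disc genes were higher in wild-type discs than brains, and all 17 measured neuronal genes were lower, among 3775 probe sets called between these tissues (1812 higher and 1963 lower in discs). Examples were nub (56.4-fold) and hh (at least 31.2-fold) higher in discs, and Syn (at least 112-fold) and Gad1 (at least 127-fold) lower. These lists were chosen for this check after their values were seen. The 3′ minus 5′ difference of the eIF-4a control probe sets, a measure of RNA breakdown, averaged 2.32 log2 in wild-type, 2.22 in lgl and 1.79 in scrib discs. In brains it averaged 2.51, 2.24 and 1.80. The actin control gave 0.84, 0.88 and 0.92 in discs and 0.98, 0.81 and 0.97 in brains. The GAPDH control gave 0.50, 0.62 and 0.34 in discs and 0.61, 0.60 and 0.61 in brains. The tissue count was 1844 with array weights by group and 1426 in the fit on its arrays alone.

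**Figure D1:**
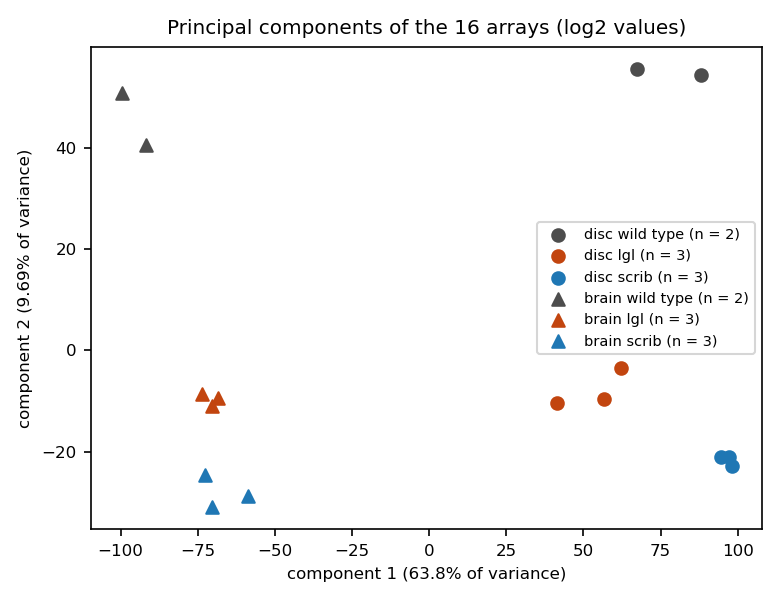
Each point is 1 array, placed by its first principal components of the log2 GCRMA values of the 8819 probe sets tested (colours and shapes give genotype and tissue). Component 1 holds 63.8% of the variance and parts discs from brains.

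The RNA of the 2 mutated genes was read first. The l(2)gl probe set averaged 10.62 ± 0.15 log2 (SD, n = 2) in wild-type discs and 3.63 ± 1.62 (SD, n = 3) in lgl discs. In brains it averaged 9.41 ± 0.68 (SD, n = 2) in wild type and 2.41 ± 0.35 (SD, n = 3) in lgl mutants. The change in discs was l(2)gl (log2 -6.99 ± 0.65 SE, at least 69.9-fold, adjusted p = 1.2e-05). The change in brains was l(2)gl (log2 -7.00 ± 0.65 SE, at least 42.6-fold, adjusted p = 2.1e-05). On the separate lgl disc arrays it read 5.47, 2.99 and 2.42, and on the lgl brain arrays 2.21, 2.82 and 2.21. In scrib mutants l(2)gl did not pass the test, at 10.77 in discs and 9.36 in brains. The brightest scrib probe set read 10.25 in wild-type and 10.11 in scrib discs (log2 change -0.15 ± 0.31 SE, adjusted p = 0.81). In brains it read 7.67 and 7.63 (-0.04 ± 0.31 SE, adjusted p = 0.95). It read 10.55 in lgl discs (adjusted p = 0.57) and 7.88 in lgl brains (adjusted p = 0.66). The labels do not say that the scrib alleles remove RNA.

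**Figure D2:**
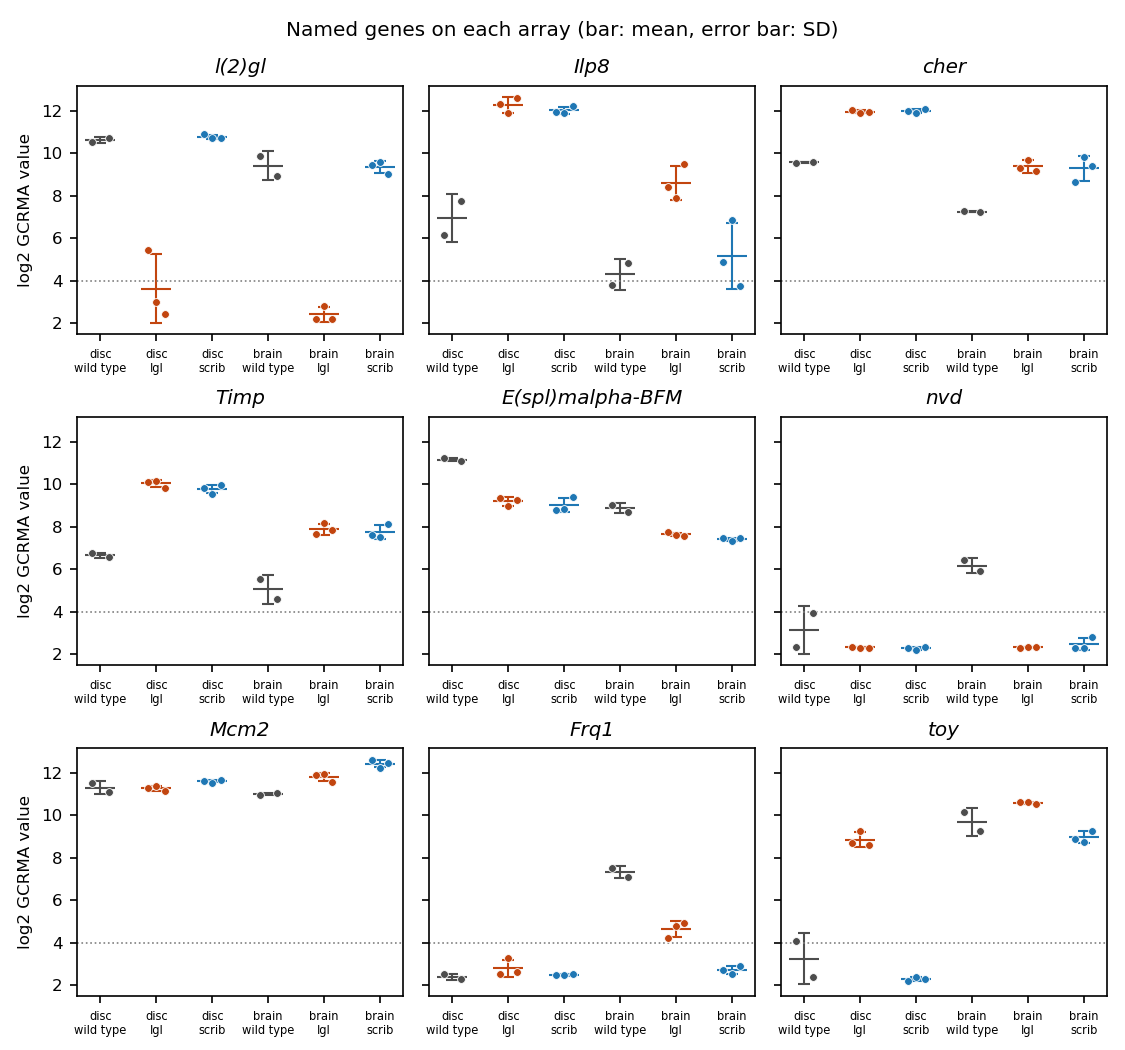
Log2 GCRMA value of 9 named genes on each of the 16 arrays by tissue and genotype (points: arrays, bar: mean, error bar: SD, dotted line: the level of 4 used as a filter). The l(2)gl RNA was at 5.47 or less on the 6 lgl arrays and at 8.93 or more on the other 10 arrays.

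The first comparison asked how lgl mutant wing discs at day 9 differed from wild-type discs at day 5 (n = 3 and 2 arrays). The relaxin-like hormone Ilp8 rose 39.8-fold, and the filamin cher rose 5.19-fold. The largest rises over all genes were led by pros (log2 6.19 ± 0.56 SE, at least 39.3-fold, adjusted p = 9.2e-06), a homeodomain factor of neural precursors, and Rnf11 (log2 5.71 ± 0.49 SE, 52.4-fold, adjusted p = 6.1e-06). Next came toy (log2 5.60 ± 0.40 SE, at least 28.1-fold, adjusted p = 1.6e-06), a Pax6 eye factor, and GstD3 (log2 5.60 ± 0.98 SE, 48.6-fold, adjusted p = 0.0015), a glutathione transferase. They also included Tdc1 (log2 5.51 ± 0.65 SE, at least 44.1-fold, adjusted p = 8.3e-05), a tyrosine decarboxylase, and Ilp8 (log2 5.32 ± 0.75 SE, 39.8-fold, adjusted p = 0.00032). The largest falls were in ImpE2 (log2 -9.88 ± 1.52 SE, at least 429-fold, adjusted p = 6e-04), an ecdysone-induced gene, and the glue gene Sgs7 (log2 -7.55 ± 2.05 SE, at least 110-fold, adjusted p = 0.022). Falls followed in l(2)gl, the serpin Spn43Aa (log2 -6.99 ± 1.2 SE, at least 103-fold, adjusted p = 0.0014), the fat body gene Fbp2 (log2 -6.93 ± 1.63 SE, at least 87.6-fold, adjusted p = 0.01) and Sgs8 (log2 -6.79 ± 1.24 SE, at least 37.2-fold, adjusted p = 0.002). Limma called 1600 of 8819 probe sets, 1059 higher and 541 lower in lgl discs. That count was 829 with array weights by group. In wild type pros, Rnf11 and toy were at least 4-fold higher in brains than in discs. The call of Sgs7 was lost with no filter (adjusted p = 0.08), with array weights by group (0.13), without wild-type disc replicate 2 (0.13), without lgl disc replicate 1 (0.059) and without lgl disc replicate 2 (0.06), range 0.001 to 0.13. The call of Fbp2 was lost with array weights by group (adjusted p = 0.12) and without wild-type disc replicate 1 (0.13), range 0.0049 to 0.13.

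Several pathway lists moved in lgl discs, given with their genes' log2 change ± SE. Of the 19 measured JNK pathway genes, 9 rose and 10 did not pass, with 10 higher adjusted over the list alone. The JNK pathway list rose (camera adjusted p = 0.00039, range 5.3e-06 to 0.29, adjusted p = 0.29 with an estimated correlation). Its members included cher (2.37 ± 0.27), Jra (1.21 ± 0.16), the fly Jun, and scaf (3.58 ± 0.50), a secreted protease homologue. Of the 14 measured basement membrane genes, 4 rose and 10 did not pass, with 7 higher adjusted over the list alone. The basement membrane list rose (camera adjusted p = 0.0062, range 0.00038 to 0.36, adjusted p = 0.36 with an estimated correlation). The basement membrane call was also lost without wild-type disc replicate 1 (adjusted p = 0.079). Its members included Timp (3.38 ± 0.28), an inhibitor of metalloproteases, and Pxn (2.47 ± 0.53). Pxn, Col4a1 and vkg are also in the hemocyte list, which rose too. Of the 20 measured wing disc genes, 9 fell and 11 did not pass, with 11 lower adjusted over the list alone. The wing disc list fell (camera adjusted p = 2e-05, range 2e-08 to 0.36, adjusted p = 0.36 with an estimated correlation). Called members included the patterning genes bi (-1.70 ± 0.22), hh (-2.19 ± 0.32) and en (-1.74 ± 0.28). Of the 12 measured Notch response genes, 5 fell and 7 did not pass, with 7 lower adjusted over the list alone. The Notch response list fell (camera adjusted p = 0.0016, range 0.00061 to 0.19, adjusted p = 0.19 with an estimated correlation). Its members included E(spl)malpha-BFM (-1.97 ± 0.19) and E(spl)mdelta-HLH (-2.19 ± 0.34). The BTB factor chinmo (2.44 ± 0.38) rose, while the JAK/STAT list that holds it did not pass. Of the genes named here, chinmo was at least 4-fold higher in wild-type brains than discs. The call of Pxn was lost without wild-type disc replicate 1 (adjusted p = 0.073), range 0.0034 to 0.073.

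Markers of other tissues moved as well in lgl discs. Of the 12 measured glial marker genes, 7 rose and 5 did not pass, with 8 higher adjusted over the list alone. The glial marker list rose (camera adjusted p = 0.0012, range 5.8e-05 to 0.19, adjusted p = 0.19 with an estimated correlation). Its members included moody (3.74 ± 0.27), a blood-brain barrier receptor, and repo (2.82 ± 0.37), the glial fate factor. Of the 17 measured neuronal marker genes, 8 rose and 9 did not pass. The neuronal marker list rose (camera adjusted p = 0.0016, range 2.2e-06 to 0.39, adjusted p = 0.39 with an estimated correlation). Its members included Syn (4.26 ± 0.26), a synaptic protein, and Gad1 (4.16 ± 0.49), which makes GABA. Of the 15 measured hemocyte marker genes, 5 rose and 10 did not pass, with 7 higher adjusted over the list alone. The hemocyte marker list rose (camera adjusted p = 0.0081, range 0.00079 to 0.42, adjusted p = 0.42 with an estimated correlation). Its members included the phagocytic receptor NimC1 (3.60 ± 0.54). Of the 8 measured eye genes, 4 rose and 4 did not pass, with 4 higher and 1 lower adjusted over the list alone. The eye list rose (camera adjusted p = 0.017, range 0.0075 to 0.29, adjusted p = 0.29 with an estimated correlation). The eye call was also lost with no filter (adjusted p = 0.087) and without wild-type disc replicate 1 (0.078). The largest was toy. Of the 6 measured fat body marker genes, 5 fell and 1 did not pass, with 6 lower adjusted over the list alone. The fat body marker list fell (camera adjusted p = 0.0014, range 4e-04 to 0.36, adjusted p = 0.36 with an estimated correlation). Its members included Fbp2 and the storage protein Lsp2 (-5.56 ± 1.48). Of the 11 measured muscle marker genes, 6 fell and 5 did not pass, with 1 higher and 8 lower adjusted over the list alone. The muscle marker list fell (camera adjusted p = 0.0018, range 1.2e-05 to 0.42, adjusted p = 0.42 with an estimated correlation). The muscle marker call was also lost without wild-type disc replicate 1 (adjusted p = 0.069). Its members included Tm2 (-3.37 ± 0.72), a tropomyosin. Of the 10 measured salivary gland marker genes, 4 fell and 6 did not pass. The salivary gland marker list fell (camera adjusted p = 0.011, range 0.0015 to 0.58, adjusted p = 0.58 with an estimated correlation). The salivary gland marker call was also lost without wild-type disc replicate 2 (adjusted p = 0.13). The 4 that fell were glue genes. The fat body median was 13.06 and 10.09 log2 on wild-type disc replicates 1 and 2 and 8.34, 4.64 and 6.85 on the lgl disc arrays. The neuronal median was 3.92 and 2.42 on the wild-type and 4.89, 5.60 and 4.46 on the lgl disc arrays. Both wild-type disc arrays also read 4 or more for 6 of the 12 glial, 2 of the 17 neuronal and 11 of the 15 hemocyte markers. Without the probe sets at least 4-fold higher in wild-type brain than disc, an alternative chosen after seeing the data, 1235 probe sets were called. The call of Lsp2 was lost with no filter (adjusted p = 0.072), with array weights by group (0.17), without wild-type disc replicate 1 (0.19) and without lgl disc replicate 2 (0.073), range 0.015 to 0.19. The log2 change without wild-type disc replicate 1 was -1.67 for Tm2. The log2 change without wild-type disc replicate 2 was -5.08 for Tm2.

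**Figure D3:**
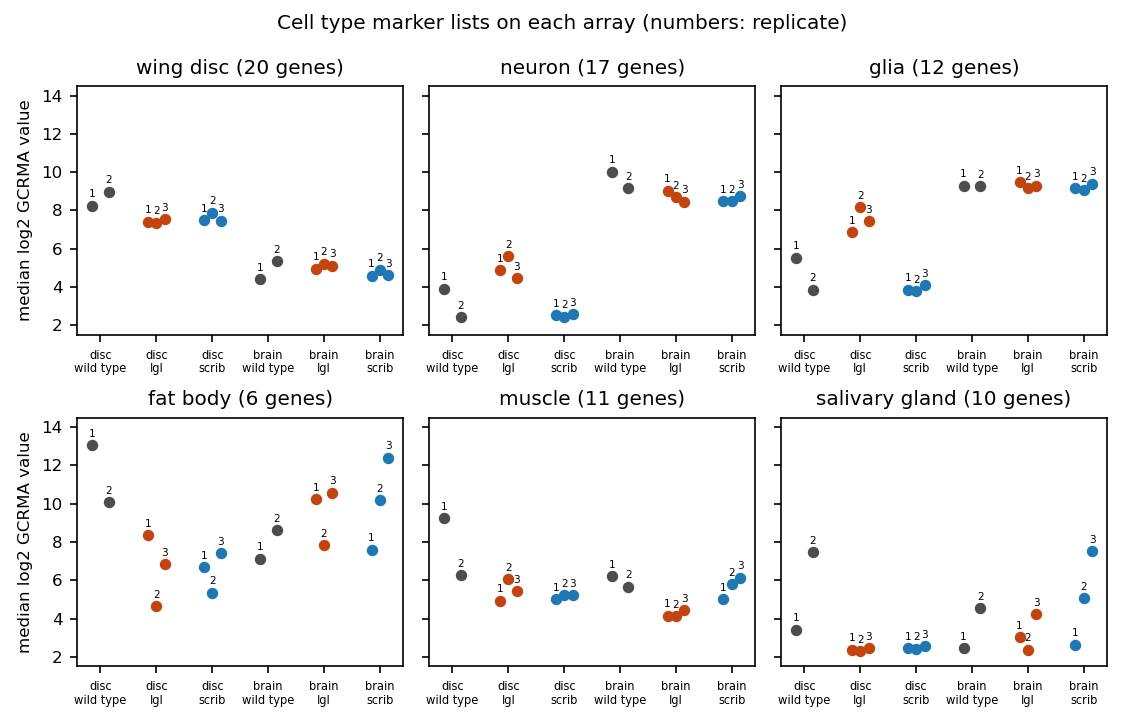
Median log2 GCRMA value of 6 marker lists on each array by tissue and genotype (points: arrays, numbers: replicates). The fat body median was 13.06 and 10.09 on the wild-type disc arrays and at most 8.34 on the 6 mutant disc arrays.

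The other 14 tested lists did not pass in lgl discs. They include DNA replication (limma called 0 of 22, 2 at unadjusted p below 0.05, camera adjusted p = 0.27), mitosis (2 lower of 17, 1 lower adjusted over the list alone, camera adjusted p = 0.3), Hippo pathway (3 higher of 13, camera adjusted p = 0.36) and cell polarity (1 higher and 2 lower of 16, camera adjusted p = 0.82, tested direction up, median log2 0.24, mean log2 -0.18).

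The next comparison set scrib mutant wing discs at day 9 against the same wild-type discs (n = 3 and 2 arrays). The FGF ligand bnl rose at least 43.7-fold, and Ilp8 rose 33.8-fold. The largest rises were led by Cpr64Ac (log2 6.99 ± 0.90 SE, 127-fold, adjusted p = 0.00018), a cuticle protein gene, and Cyp6a20 (log2 6.61 ± 0.73 SE, at least 32.1-fold, adjusted p = 5.2e-05), a cytochrome P450. Next came Zip102B (log2 6.59 ± 0.16 SE, at least 76.1-fold, adjusted p = 3.3e-11), a zinc transporter, and bnl (log2 5.56 ± 0.39 SE, at least 43.7-fold, adjusted p = 1.1e-06). Then followed Tdc1 (log2 5.47 ± 0.65 SE, at least 42.8-fold, adjusted p = 8.7e-05) and the dynein assembly factor Dnaaf3 (log2 5.43 ± 0.24 SE, at least 12.5-fold, adjusted p = 1.6e-08). The largest falls were in ImpE2 (log2 -10.13 ± 1.52 SE, at least 515-fold, adjusted p = 0.00051) and Spn43Aa (log2 -8.22 ± 1.2 SE, at least 158-fold, adjusted p = 0.00042). The fat body gene Fbp1 (log2 -7.21 ± 1.70 SE, at least 125-fold, adjusted p = 0.0089) and Sgs8 (log2 -6.44 ± 1.24 SE, at least 37.2-fold, adjusted p = 0.0028) fell next. The serpin Spn100A (log2 -6.40 ± 0.63 SE, at least 28.2-fold, adjusted p = 2.1e-05) and the sulfotransferase St2 (log2 -6.32 ± 0.89 SE, at least 39.6-fold, adjusted p = 0.00032) completed them. Limma called 2042 probe sets, 1108 higher and 934 lower in scrib discs. That count was 880 with array weights by group and 1120 with a fold of at least 2 as well. The call of Fbp1 was lost with array weights by group (adjusted p = 0.11) and without wild-type disc replicate 1 (0.053), range 0.0029 to 0.11.

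With the preset correlation, JNK, glycolysis and immune lists rose in scrib discs and ecdysone, Notch and wing disc lists fell. Among the 19 measured JNK pathway genes, 9 rose, 2 fell and 8 did not pass. The JNK pathway list rose (camera adjusted p = 0.0062, range 0.00017 to 0.42, adjusted p = 0.42 with an estimated correlation). The JNK pathway call was also lost without wild-type disc replicate 1 (adjusted p = 0.075). Its members included cher (2.40 ± 0.27), Jra (1.36 ± 0.16), Irbp18 (1.77 ± 0.26), a bZIP factor, and Ilp8 (5.08 ± 0.75). Among the 11 measured glycolysis genes, 5 rose and 6 did not pass, with 7 higher and 1 lower adjusted over the list alone. The glycolysis list rose (camera adjusted p = 0.01, range 0.002 to 0.38, adjusted p = 0.38 with an estimated correlation). Called members included the sugar transporter Tret1-1 (2.73 ± 0.39), also in the glial list, and phosphofructokinase, Pfk (1.35 ± 0.26). Among the 9 measured immune genes, 2 rose and 7 did not pass, with 3 higher adjusted over the list alone. The immune list rose (camera adjusted p = 0.038, range 0.018 to 0.43, adjusted p = 0.43 with an estimated correlation). The immune call was also lost with no filter (adjusted p = 0.07), with the filter at 6 (0.11), with array weights by group (0.076), without wild-type disc replicate 1 (0.078), without wild-type disc replicate 2 (0.071) and without scrib disc replicate 2 (0.066). The cecropin CecB (2.64 ± 0.18) had the smallest adjusted p. Among the 14 measured ecdysone response genes, 1 rose, 5 fell and 8 did not pass, with 1 higher and 7 lower adjusted over the list alone. The ecdysone response list fell (camera adjusted p = 0.037, range 0.00089 to 0.47, adjusted p = 0.47 with an estimated correlation). The ecdysone response call was also lost without wild-type disc replicate 2 (adjusted p = 0.13). Falls included ImpE1 (-4.78 ± 0.81), and the rise was in ImpL2 (4.04 ± 0.46), which binds insulin-like peptides. Among the 12 measured Notch response genes, 5 fell and 7 did not pass. The Notch response list fell (camera adjusted p = 0.017, range 0.0074 to 0.26, adjusted p = 0.26 with an estimated correlation). Its members included E(spl)malpha-BFM (-2.14 ± 0.19), E(spl)m7-HLH (-1.87 ± 0.24) and E(spl)m4-BFM (-3.75 ± 0.52). Among the 20 measured wing disc genes, 5 fell and 15 did not pass. The wing disc list fell (camera adjusted p = 0.0063, range 4.8e-05 to 0.55, adjusted p = 0.55 with an estimated correlation). The wing disc call was also lost without wild-type disc replicate 2 (adjusted p = 0.46). Its members included bi (-1.52 ± 0.22) and en (-1.63 ± 0.28).

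Lists of fat body, muscle and salivary gland markers also fell in scrib discs with the preset correlation. Among the 6 measured fat body marker genes, 5 fell and 1 did not pass, with 6 lower adjusted over the list alone. The fat body marker list fell (camera adjusted p = 0.00046, range 0.00022 to 0.36, adjusted p = 0.36 with an estimated correlation). Its members included the lipid carrier apolpp (-6.30 ± 0.69) and Mtp (-1.08 ± 0.17). Among the 11 measured muscle marker genes, 9 fell and 2 did not pass. The muscle marker list fell (camera adjusted p = 0.00046, range 1.4e-06 to 0.38, adjusted p = 0.38 with an estimated correlation). Its members included bt (-3.62 ± 0.60). Among the 10 measured salivary gland marker genes, 3 fell and 7 did not pass, with 4 lower adjusted over the list alone. The salivary gland marker list fell (camera adjusted p = 0.04, range 0.0067 to 0.65, adjusted p = 0.65 with an estimated correlation). The salivary gland marker call was also lost with no filter (adjusted p = 0.07), without wild-type disc replicate 2 (0.23), without scrib disc replicate 1 (0.078) and without scrib disc replicate 2 (0.054). The fat body median was 6.68, 5.35 and 7.41 log2 on the scrib disc arrays, beside 13.06 and 10.09 in wild type. The muscle median was 5.02, 5.22 and 5.21, beside 9.24 and 6.26. Within lists that did not pass, Timp (3.13 ± 0.28) and chinmo (2.10 ± 0.38) rose, and the small heat shock protein Hsp27 (-2.70 ± 0.31) and the RNA-binding Syp (-2.15 ± 0.32) fell. The metalloprotease Mmp2 (-3.10 ± 0.48), in the JNK and basement membrane lists, fell against the direction of the JNK list. The other 16 tested lists did not pass.

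In lgl mutant brain complexes against wild type (n = 3 and 2 arrays), the Hippo pathway gene fj rose at least 14.4-fold and the brain hormone Ptth fell 8.11-fold. The largest rises were led by Cpr64Aa (log2 8.88 ± 0.63 SE, at least 214-fold, adjusted p = 2.2e-06), a cuticle protein gene, and Spn47C (log2 5.63 ± 0.31 SE, at least 22.6-fold, adjusted p = 3.3e-07), a serpin. Others were Drs (log2 5.31 ± 1.08 SE, at least 17.9-fold, adjusted p = 0.0041), an antifungal peptide, and kek5 (log2 5.16 ± 0.31 SE, at least 35-fold, adjusted p = 5.2e-07), a transmembrane protein. The remaining rises were GstD3 (log2 4.87 ± 0.98 SE, at least 18.7-fold, adjusted p = 0.0039) and Tdc1 (log2 4.82 ± 0.65 SE, at least 18-fold, adjusted p = 0.00032). Among the largest falls were the ecdysone synthesis genes spok (log2 -8.07 ± 1.48 SE, at least 128-fold, adjusted p = 0.0023) and phtm (log2 -4.91 ± 0.83 SE, at least 17-fold, adjusted p = 0.0014). The neuropeptide precursor Nplp4 (log2 -6.11 ± 0.95 SE, at least 39-fold, adjusted p = 0.00081), the chaperone Hsc70-2 (log2 -5.92 ± 0.56 SE, at least 17.5-fold, adjusted p = 2.6e-05), ImpE2 (log2 -5.06 ± 1.52 SE, at least 10.3-fold, adjusted p = 0.029) and l(2)gl completed them. Limma called 2228 probe sets, 1231 higher and 997 lower. The count became 254 with array weights by group, 1363 in the fit on its arrays alone, 1135 with a fold of at least 2 as well, 1204 without wild-type brain replicate 1 and 3769 without wild-type brain replicate 2. The call of ImpE2 was lost with no filter (adjusted p = 0.093), with array weights by group (0.47), without wild-type brain replicate 1 (0.056), without wild-type brain replicate 2 (0.12), without lgl brain replicate 1 (0.068), without lgl brain replicate 2 (0.067) and without lgl brain replicate 3 (0.059), range 0.0036 to 0.47. Array weights by group ended the calls of Drs (adjusted p range 0.00024 to 0.25), GstD3 (0.0011 to 0.089), spok (0.0019 to 0.083), phtm (0.00075 to 0.087) and Nplp4 (0.00046 to 0.13). The log2 change without wild-type brain replicate 2 was 3.04 for GstD3.

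Lists of growth and division rose in lgl brains with the preset correlation. Of the 13 measured Hippo pathway genes, 8 rose and 5 did not pass. The Hippo pathway list rose (camera adjusted p = 0.0012, range 6.1e-05 to 0.42, adjusted p = 0.42 with an estimated correlation). Its members included fj (3.91 ± 0.24) and vg (3.28 ± 0.34). Of the 17 measured mitosis genes, 7 rose and 10 did not pass, with 9 higher adjusted over the list alone. The list rose (camera adjusted p = 0.0027, range 4.5e-05 to 0.36, adjusted p = 0.36 with an estimated correlation). Its members included feo (1.28 ± 0.19), a spindle midzone protein. Of the 22 measured DNA replication genes, 7 rose and 15 did not pass, with 8 higher adjusted over the list alone. The list rose (camera adjusted p = 0.011, range 0.00045 to 0.5, adjusted p = 0.5 with an estimated correlation). Its members included a helicase subunit, Mcm2 (0.80 ± 0.17). Of the 11 measured neuroblast marker genes, 6 rose, 1 fell and 4 did not pass, with 7 higher and 1 lower adjusted over the list alone. The list rose (camera adjusted p = 0.017, range 0.0026 to 0.42, adjusted p = 0.42 with an estimated correlation). The neuroblast marker call was also lost without wild-type brain replicate 1 (adjusted p = 0.087) and without wild-type brain replicate 2 (0.064). The factor grh (2.34 ± 0.20) rose and l(1)sc (-2.23 ± 0.32) fell. Of the 14 measured basement membrane genes, 5 rose and 9 did not pass, with 5 higher and 1 lower adjusted over the list alone. The basement membrane list rose (camera adjusted p = 0.043, range 0.012 to 0.46, adjusted p = 0.46 with an estimated correlation). The basement membrane call was also lost with the filter at 6 (adjusted p = 0.053), without wild-type brain replicate 1 (0.13), without wild-type brain replicate 2 (0.064) and without lgl brain replicate 2 (0.085). Its members included Timp (2.83 ± 0.28) and the laminin LanA (1.37 ± 0.19). Weighting arrays by group ended the call of Mcm2 (adjusted p range 0.0022 to 0.16).

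Neuronal, ring gland, glycolysis and muscle lists fell in lgl brains with the preset correlation. Of the 17 measured neuronal marker genes, 10 fell and 7 did not pass, with 11 lower adjusted over the list alone. The neuronal marker list fell (camera adjusted p = 6.7e-06, range 1.6e-07 to 0.26, adjusted p = 0.26 with an estimated correlation). Its members included the calcium sensor Frq1 (-2.68 ± 0.25) and the exchanger Nckx30C (-1.89 ± 0.23). Of the 8 measured ring gland genes, 6 fell and 2 did not pass, with 1 higher and 6 lower adjusted over the list alone. The ring gland list fell (camera adjusted p = 0.00034, range 0.00014 to 0.24, adjusted p = 0.24 with an estimated correlation). Its members included the ecdysone synthesis enzyme nvd (-3.85 ± 0.34). The list also holds Ptth (-3.02 ± 0.22), which is made in brain neurons. The share of ring gland in the brain complexes is unknown, so it and the activity of these genes, spok and phtm included, are not told apart. Of the 11 measured glycolysis genes, 3 fell and 8 did not pass, with 7 lower adjusted over the list alone. The glycolysis list fell (camera adjusted p = 0.0045, range 0.00087 to 0.36, adjusted p = 0.36 with an estimated correlation). Its members included a glucose transporter, Glut1 (-3.79 ± 0.45), of which another probe set rose (1.26 ± 0.38, adjusted p = 0.028). Limma called 0 of the 11 measured muscle marker genes (3 at unadjusted p below 0.05), and 0 adjusted over the list alone. The muscle marker list fell (camera adjusted p = 0.043, range 0.028 to 0.63, adjusted p = 0.63 with an estimated correlation). The muscle marker call was also lost with array weights by group (adjusted p = 0.059), without wild-type brain replicate 1 (0.15), without wild-type brain replicate 2 (0.12), without lgl brain replicate 1 (0.06) and without lgl brain replicate 2 (0.076). The JNK members cher (2.13 ± 0.27) and scaf (3.78 ± 0.50) rose and the Notch response gene E(spl)m5-HLH (-3.99 ± 0.23) fell. Neither the JNK list (camera adjusted p = 0.14) nor the Notch response list (camera adjusted p = 0.052) passed, nor did the other 14 tested lists.

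In scrib mutant brain complexes against wild type (n = 3 and 2 arrays), the helicase gene Mcm2 rose 2.7-fold, and Frq1 fell at least 10-fold. The largest rises were led by ng3 (log2 6.63 ± 1.59 SE, at least 58.1-fold, adjusted p = 0.0065), a salivary gland gene, and Zip102B (log2 6.48 ± 0.16 SE, at least 71.1-fold, adjusted p = 3.5e-11). The antimicrobial peptides Def (log2 6.18 ± 0.90 SE, at least 20.9-fold, adjusted p = 0.00028) and Drs (log2 5.35 ± 1.08 SE, at least 18.3-fold, adjusted p = 0.0024) were among them. So were Marf1 (log2 5.96 ± 0.32 SE, at least 29.2-fold, adjusted p = 9.2e-08) and Tektin-C (log2 5.76 ± 0.14 SE, at least 17.8-fold, adjusted p = 3.5e-11), a ciliary protein. The largest falls began with Jhbp2 (log2 -5.51 ± 0.77 SE, at least 24.6-fold, adjusted p = 0.00021) and spok (log2 -5.26 ± 1.48 SE, at least 37.5-fold, adjusted p = 0.015). Further falls were in ImpE2 (log2 -5.08 ± 1.52 SE, at least 10.3-fold, adjusted p = 0.02) and Spn43Aa (log2 -5.01 ± 1.2 SE, at least 16.2-fold, adjusted p = 0.0066). The last were NimA (log2 -4.88 ± 0.25 SE, at least 14.1-fold, adjusted p = 6.9e-08) and Frq1 (log2 -4.59 ± 0.25 SE, at least 10-fold, adjusted p = 1.1e-07). Limma called 3073 probe sets, 1740 higher and 1333 lower. That count was 780 with array weights by group and 1673 with a fold of at least 2 as well. The salivary gland median was 2.63, 5.06 and 7.51 log2 on the scrib brain arrays, beside 2.44 and 4.56 in wild type. The fat body median was 7.60, 10.19 and 12.41, beside 7.13 and 8.63. The call of ng3 was lost with array weights by group (adjusted p = 0.25) and without wild-type brain replicate 1 (0.055), range 0.0017 to 0.25. The call of spok was lost with no filter (adjusted p = 0.057), with array weights by group (0.19), without wild-type brain replicate 1 (0.077) and without scrib brain replicate 1 (0.055), range 0.011 to 0.19. The call of ImpE2 was lost with no filter (adjusted p = 0.072), with array weights by group (0.42) and without wild-type brain replicate 2 (0.12), range 0.0019 to 0.42. The call of Spn43Aa was lost with array weights by group (adjusted p = 0.17) and without wild-type brain replicate 2 (0.074), range 0.0012 to 0.17. Array weights by group ended the calls of Def (adjusted p range 0.00015 to 0.058) and Drs (0.0017 to 0.19). The log2 change without wild-type brain replicate 2 was -3.15 for Spn43Aa.

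Division and Hippo lists rose in scrib brains with the preset correlation. Among the 22 measured DNA replication genes, 15 rose and 7 did not pass, with 18 higher adjusted over the list alone. The DNA replication list rose (camera adjusted p = 4.6e-06, range 2.8e-10 to 0.26, adjusted p = 0.26 with an estimated correlation). Its members included Mcm2 (1.43 ± 0.17), dpa (1.36 ± 0.17), Mcm5 (1.24 ± 0.16) and the origin protein Orc1 (1.54 ± 0.19). Among the 17 measured mitosis genes, 11 rose and 6 did not pass, with 12 higher adjusted over the list alone. The mitosis list rose (camera adjusted p = 0.00032, range 7.6e-07 to 0.27, adjusted p = 0.27 with an estimated correlation). Its members included feo (1.75 ± 0.19) and the kinesin ncd (1.38 ± 0.17). Among the 11 measured neuroblast marker genes, 6 rose and 5 did not pass, with 7 higher adjusted over the list alone. The neuroblast marker list rose (camera adjusted p = 0.037, range 0.0078 to 0.42, adjusted p = 0.42 with an estimated correlation). The neuroblast marker call was also lost with array weights by group (adjusted p = 0.068), without wild-type brain replicate 1 (0.14), without wild-type brain replicate 2 (0.082) and without scrib brain replicate 3 (0.098). Its members included grh (1.82 ± 0.20). Among the 13 measured Hippo pathway genes, 7 rose, 1 fell and 5 did not pass. The Hippo pathway list rose (camera adjusted p = 0.022, range 0.0036 to 0.59, adjusted p = 0.59 with an estimated correlation). The Hippo pathway call was also lost without wild-type brain replicate 1 (adjusted p = 0.16). Its members included fj (4.0 ± 0.24).

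Neuronal, ring gland, ecdysone and Notch lists fell in scrib brains with the preset correlation. Among the 17 measured neuronal marker genes, 11 fell and 6 did not pass. The neuronal marker list fell (camera adjusted p = 4.9e-07, range 2.8e-10 to 0.26, adjusted p = 0.26 with an estimated correlation). Its members included unc-13 (-1.86 ± 0.27), a synaptic release factor, and VGlut (-1.90 ± 0.31), a glutamate transporter. Among the 8 measured ring gland genes, 5 fell and 3 did not pass, with 6 lower adjusted over the list alone. The ring gland list fell (camera adjusted p = 0.0016, range 0.00041 to 0.26, adjusted p = 0.26 with an estimated correlation). Its members included nvd (-3.70 ± 0.34), and Ptth (-2.34 ± 0.22) of the brain neurons. Here too the share of ring gland is unknown. Among the 14 measured ecdysone response genes, 7 fell and 7 did not pass, with 1 higher and 7 lower adjusted over the list alone. The ecdysone response list fell (camera adjusted p = 0.018, range 0.0028 to 0.42, adjusted p = 0.42 with an estimated correlation). The ecdysone response call was also lost without wild-type brain replicate 2 (adjusted p = 0.29). Among the 12 measured Notch response genes, 2 rose, 5 fell and 5 did not pass, with 3 higher and 7 lower adjusted over the list alone. The Notch response list fell (camera adjusted p = 0.04, range 0.022 to 0.26, adjusted p = 0.26 with an estimated correlation). The Notch response call was also lost with array weights by group (adjusted p = 0.059), without wild-type brain replicate 1 (0.082), without wild-type brain replicate 2 (0.13) and without scrib brain replicate 2 (0.058). Falls included E(spl)m5-HLH (-3.12 ± 0.23) and E(spl)malpha-BFM (-1.47 ± 0.19). The RNA-binding Imp (-2.98 ± 0.38), a factor of early neuroblasts, fell within a temporal identity list that did not pass. The other 17 tested lists did not pass. Without either of the wild-type brain arrays, 5 lists were called in place of 8.

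**Figure D4:**
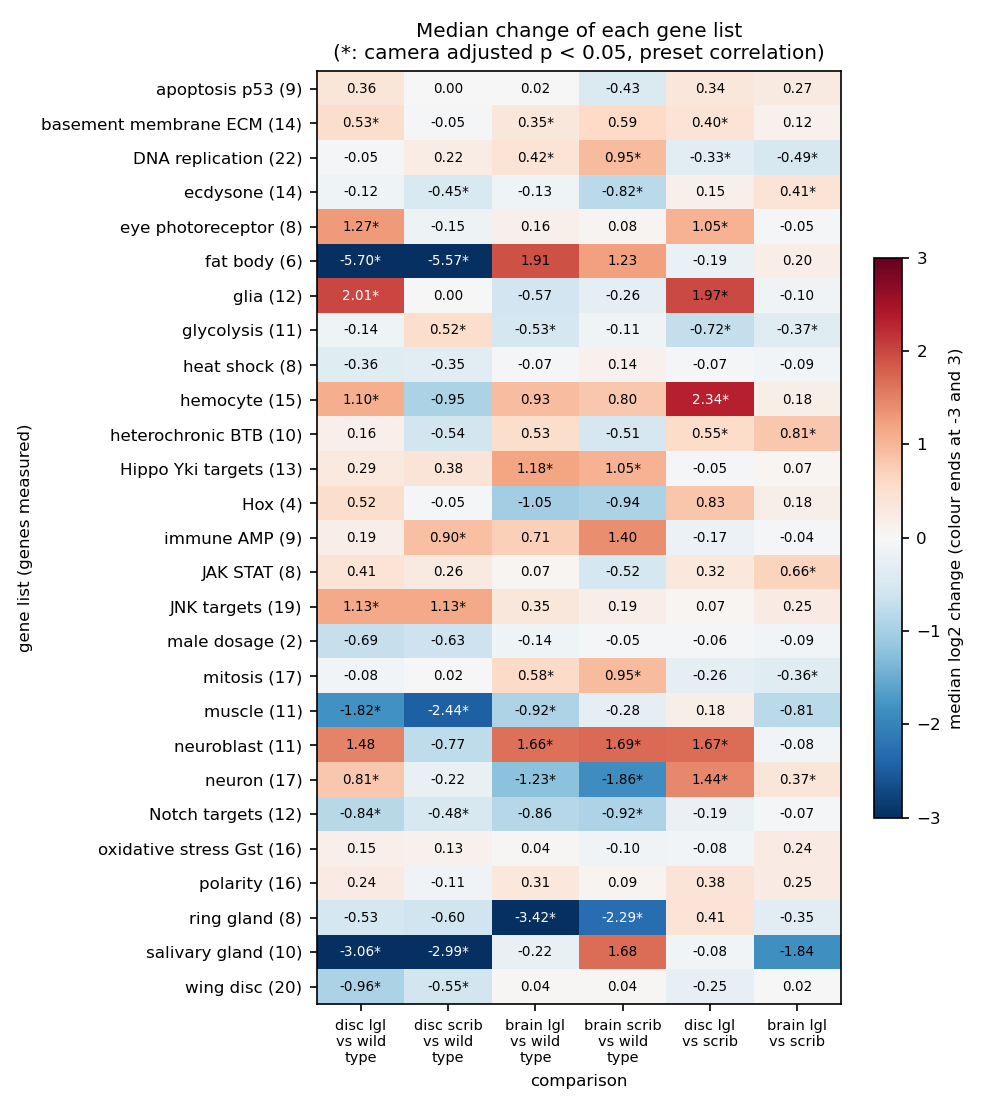
Median log2 change of the 27 gene lists in 6 comparisons (columns, first group minus second). An asterisk marks a camera adjusted p below 0.05 with the preset correlation, and 0 lists keep it with an estimated correlation (unadjusted p below 0.05 for 1 to 6 lists per comparison).

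Many probe sets were called in both mutants. In discs 812 probe sets were called in the same direction in lgl and scrib mutants, 479 higher and 333 lower, and 29 in opposite directions. Independent calls would share 133 higher and 57 lower. In brains 1633 were shared, 942 higher and 691 lower, with 16 in opposite directions. Independent calls in brains would share 243 and 151. Both comparisons use the same wild-type arrays, which alone makes the effects correlate. In 100 simulated draws with shared controls and no effect, the overlap was at most 3 in discs and 9 in brains. With no effect few calls arise at all, and independent calls leave out the shared controls, so the excess over either is not a count of shared effects. Across probe sets, which are not independent replicates, the correlation of the effects was 0.60 in discs and 0.73 in brains, below the simulated 0.84 and 0.81, so it does not measure sharing. The covariance exceeded the simulated one by 0.457 and 0.519. The controls were not split (1 array left per mutant). They and the mutants' shared age may give part of the excess. The disc overlap was 371 with array weights by group and 489 with a fold of at least 2 as well. The brain overlap was 179 with array weights by group, 992 in the fit on its arrays alone, 758 with a fold of at least 2 as well, 913 without wild-type brain replicate 1 and 2888 without wild-type brain replicate 2.

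Of 7213 genes, 137 rose and 60 fell in all 4 mutant groups (all day 9). Chosen by rule were Tdc1, Fbxl4, flap, Pvf1, yellow-b, scaf, Timp and Patr-1 upward. In lgl discs, scrib discs, lgl brains and scrib brains in turn, the log2 change of Timp was 3.38, 3.13, 2.83 and 2.70 (SE 0.28). Fbxl4, below 4 in wild type, rose at least 5.5-fold, 6.06-fold, 6.5-fold and 9.77-fold. Downward they were ImpE2, E(spl)mdelta-HLH, sro, fmt, E(spl)malpha-BFM, not, Dnaaf5 and bnb. The Notch response gene E(spl)malpha-BFM changed by -1.97, -2.14, -1.24 and -1.47 (SE 0.19), and fmt by -2.57, -1.56, -3.41 and -1.71 (SE 0.21). The call of ImpE2 in lgl brains was lost without wild-type brain replicate 1 (adjusted p = 0.056), without wild-type brain replicate 2 (0.12), without lgl brain replicate 1 (0.068), without lgl brain replicate 2 (0.067) and without lgl brain replicate 3 (0.059), range 0.0036 to 0.47. The call of ImpE2 in scrib brains was lost without wild-type brain replicate 2 (adjusted p = 0.12), range 0.0019 to 0.42. The call of Dnaaf5 in lgl brains was lost without wild-type brain replicate 1 (adjusted p = 0.092), range 0.00083 to 0.15. The call of Dnaaf5 in scrib brains was lost without wild-type brain replicate 1 (adjusted p = 0.1), range 0.00097 to 0.14. The call of bnb in lgl discs was lost without wild-type disc replicate 2 (adjusted p = 0.16), without lgl disc replicate 1 (0.066) and without lgl disc replicate 2 (0.081), range 0.012 to 0.16. The call of bnb in scrib discs was lost without wild-type disc replicate 2 (adjusted p = 0.098), range 0.0051 to 0.098. The call of bnb in lgl brains was lost without wild-type brain replicate 2 (adjusted p = 0.28), without lgl brain replicate 1 (0.081), without lgl brain replicate 2 (0.091) and without lgl brain replicate 3 (0.12), range 0.019 to 0.39. The call of bnb in scrib brains was lost without wild-type brain replicate 2 (adjusted p = 0.055), range 0.0027 to 0.15. Array weights by group ended at least 1 of the 4 calls of flap, Pvf1, ImpE2, E(spl)mdelta-HLH, sro, E(spl)malpha-BFM, not, Dnaaf5 and bnb. Without wild-type disc replicate 1 the log2 change was 2.43 for Pvf1 in lgl discs and 2.94 for Pvf1 in scrib discs. Without wild-type brain replicate 1 the log2 change was 1.88 for yellow-b in lgl brains, 1.84 for yellow-b in scrib brains, -0.75 for Dnaaf5 in lgl brains and -0.64 for Dnaaf5 in scrib brains. Without wild-type brain replicate 2 the log2 change was -0.69 for not in lgl brains, -0.70 for not in scrib brains and -0.60 for bnb in lgl brains.

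The mutants share age, so the direct comparison of lgl with scrib discs (n = 3 arrays each) does not carry the difference in days. The largest differences toward lgl were Obp44a (log2 8.22 ± 1.72 SE, at least 286-fold, adjusted p = 0.0048), an odorant-binding protein, and eEF1alpha2 (log2 7.02 ± 0.65 SE, at least 101-fold, adjusted p = 1.1e-05), an elongation factor. The transcription factors pros (log2 6.96 ± 0.50 SE, at least 40.4-fold, adjusted p = 1.2e-06) and toy (log2 6.55 ± 0.36 SE, at least 29-fold, adjusted p = 1.5e-07) followed. Toward scrib they were l(2)gl (log2 -7.15 ± 0.58 SE, at least 77.9-fold, adjusted p = 3.2e-06) and Zip102B (log2 -6.42 ± 0.14 SE, at least 76.1-fold, adjusted p = 1.1e-11). After them came tut (log2 -6.23 ± 0.40 SE, at least 29.5-fold, adjusted p = 4.7e-07) and Hsc70-2 (log2 -6.21 ± 0.50 SE, at least 26.4-fold, adjusted p = 3.2e-06). Limma called 1805 probe sets, 1052 higher in lgl and 753 higher in scrib discs. The count became 3529 with array weights by group, 933 with a fold of at least 2 as well, 1202 without lgl disc replicate 2, 1165 without lgl disc replicate 3 and 1050 without scrib disc replicate 3. Without the brain-enriched probe sets it was 1378. The 3′ minus 5′ difference of eIF-4a was 2.22 in lgl and 1.79 in scrib discs (other controls above). In wild type Obp44a, eEF1alpha2, pros and toy were at least 4-fold higher in brains than in discs, and neural marker lists were higher on the same lgl disc arrays. The call of Obp44a was lost in the fit on its arrays alone (adjusted p = 0.054), range 0.00015 to 0.054.

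Marker lists of neural cells, blood cells and eye differed between the mutant discs with the preset correlation, given with log2 differences of lgl minus scrib ± SE. Of the 17 measured neuronal marker genes, 10 were higher in lgl and 7 did not pass, with 11 higher in lgl adjusted over the list alone. The neuronal marker list was higher in lgl (camera adjusted p = 1.2e-05, range 4.6e-07 to 0.26, adjusted p = 0.26 with an estimated correlation). Its members included Syn (4.39 ± 0.23), Gad1 (5.27 ± 0.44), Appl (3.77 ± 0.48) and cpx (5.39 ± 0.75). Of the 15 measured hemocyte marker genes, 11 were higher in lgl and 4 did not pass, with 12 higher in lgl adjusted over the list alone. The hemocyte marker list was higher in lgl (camera adjusted p = 1.4e-05, range 1.6e-07 to 0.26, adjusted p = 0.26 with an estimated correlation). Its members included NimC1 (2.96 ± 0.48) and Hml (3.40 ± 0.58). Of the 12 measured glial marker genes, 7 were higher in lgl, 1 was higher in scrib and 4 did not pass. The glial marker list was higher in lgl (camera adjusted p = 0.0027, range 0.00021 to 0.19, adjusted p = 0.19 with an estimated correlation). Its members included Gs2 (4.44 ± 0.46) and repo (3.17 ± 0.33). Of the 11 measured neuroblast marker genes, 5 were higher in lgl and 6 did not pass, with 7 higher in lgl adjusted over the list alone. The neuroblast marker list was higher in lgl (camera adjusted p = 0.0072, range 0.00028 to 0.36, adjusted p = 0.36 with an estimated correlation). Its members included mira (3.68 ± 0.75) and wor (3.60 ± 0.75). Of the 8 measured eye genes, 4 were higher in lgl and 4 did not pass. The eye list was higher in lgl (camera adjusted p = 0.006, range 0.0014 to 0.26, adjusted p = 0.26 with an estimated correlation). Its members included dac (6.43 ± 0.56), like toy, ey and oc at least 4-fold higher in wild-type brains than discs. The neuronal median was 4.89, 5.60 and 4.46 log2 on the lgl disc arrays and 2.55, 2.46 and 2.60 on the scrib ones. The glial median was 6.88, 8.16 and 7.43 against 3.86, 3.78 and 4.11.

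Lists of matrix, temporal identity and metabolism also differed between the mutant discs in that test. Of the 14 measured basement membrane genes, 6 were higher in lgl, 1 was higher in scrib and 7 did not pass, with 7 higher in lgl and 1 higher in scrib adjusted over the list alone. The basement membrane list was higher in lgl (camera adjusted p = 0.0048, range 0.00036 to 0.36, adjusted p = 0.36 with an estimated correlation). Its members included the collagens Col4a1 (2.17 ± 0.34) and vkg (2.21 ± 0.37), which are also in the hemocyte list, and perlecan, trol (2.40 ± 0.27). Of the 10 measured temporal identity genes, 4 were higher in lgl and 6 did not pass. The temporal identity list was higher in lgl (camera adjusted p = 0.038, range 0.013 to 0.29, adjusted p = 0.29 with an estimated correlation). The temporal identity call was also lost without lgl disc replicate 2 (adjusted p = 0.065) and without scrib disc replicate 1 (0.065). Its members included cas (4.38 ± 0.55). Of the 11 measured glycolysis genes, 6 were higher in scrib and 5 did not pass, with 9 higher in scrib adjusted over the list alone. The glycolysis list was higher in scrib (camera adjusted p = 0.00016, range 2.1e-05 to 0.26, adjusted p = 0.26 with an estimated correlation). Its members included Pfk (-1.56 ± 0.23) and the enolase Eno (-0.79 ± 0.14). Of the 22 measured DNA replication genes, 2 were higher in scrib and 20 did not pass. The DNA replication list was higher in scrib (camera adjusted p = 0.0033, range 0.00053 to 0.42, adjusted p = 0.42 with an estimated correlation). The cell death genes skl (2.50 ± 0.38) and egr (2.0 ± 0.33) were higher in lgl discs and CecB (-2.37 ± 0.16) was higher in scrib discs, in lists that did not pass. In wild type cas, skl and egr were at least 4-fold higher in brains than in discs, and neural marker lists were higher on the same lgl disc arrays. The other 16 tested lists did not pass.

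Between lgl and scrib brains (n = 3 arrays each), Def and Zip102B were higher in scrib brains. The largest differences toward lgl were Cpr12A (log2 6.01 ± 0.87 SE, at least 32.2-fold, adjusted p = 0.00081) and Cpr64Aa (log2 5.27 ± 0.56 SE, 38.6-fold, adjusted p = 6.6e-05), both cuticle protein genes. Next came GstD3 (log2 4.70 ± 0.88 SE, at least 22.1-fold, adjusted p = 0.0043) and Culd (log2 4.44 ± 0.34 SE, at least 20.6-fold, adjusted p = 4.5e-06). Toward scrib they were l(2)gl (log2 -6.95 ± 0.58 SE, at least 41.1-fold, adjusted p = 9.8e-06) and Hsc70-2 (log2 -6.75 ± 0.50 SE, at least 31.2-fold, adjusted p = 3.7e-06). Last came Zip102B (log2 -6.53 ± 0.14 SE, at least 71.1-fold, adjusted p = 9.2e-12) and Def (log2 -6.18 ± 0.81 SE, at least 20.9-fold, adjusted p = 0.00035). Limma called 1014 probe sets, 536 higher in lgl and 478 higher in scrib brains. The count became 1923 with array weights by group, 583 in the fit on its arrays alone, 582 with a fold of at least 2 as well, 604 without lgl brain replicate 1, 620 without lgl brain replicate 2 and 659 without scrib brain replicate 2. The 3′ minus 5′ difference of eIF-4a was 2.24 in lgl and 1.80 in scrib brains (other controls above). The call of GstD3 was lost in the fit on its arrays alone (adjusted p = 0.059), range 0.00032 to 0.059.

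With the preset correlation, division and metabolism lists were higher in scrib brains, and identity and hormone response lists in lgl brains. Among the 22 measured DNA replication genes, 10 were higher in scrib and 12 did not pass, with 17 higher in scrib adjusted over the list alone. The DNA replication list was higher in scrib (camera adjusted p = 4.6e-06, range 2.8e-10 to 0.26, adjusted p = 0.26 with an estimated correlation). Among the 17 measured mitosis genes, 2 were higher in scrib and 15 did not pass, with 3 higher in scrib adjusted over the list alone. The mitosis list was higher in scrib (camera adjusted p = 0.014, range 0.00081 to 0.42, adjusted p = 0.42 with an estimated correlation). The mitosis call was also lost without scrib brain replicate 1 (adjusted p = 0.081). Limma called 0 of the 11 measured glycolysis genes (5 at unadjusted p below 0.05), with 3 higher in scrib adjusted over the list alone. The glycolysis list was higher in scrib (camera adjusted p = 0.03, range 0.0025 to 0.42, adjusted p = 0.42 with an estimated correlation). The glycolysis call was also lost without scrib brain replicate 2 (adjusted p = 0.09). Among the 10 measured temporal identity genes, 4 were higher in lgl and 6 did not pass, with 5 higher in lgl adjusted over the list alone. The temporal identity list was higher in lgl (camera adjusted p = 0.0016, range 0.00034 to 0.23, adjusted p = 0.23 with an estimated correlation). Its members included svp (1.59 ± 0.29), a nuclear receptor. Among the 17 measured neuronal marker genes, 3 were higher in lgl and 14 did not pass, with 5 higher in lgl adjusted over the list alone. The neuronal marker list was higher in lgl (camera adjusted p = 0.0042, range 2e-04 to 0.42, adjusted p = 0.42 with an estimated correlation). Its members included Frq1 (1.91 ± 0.23). Among the 14 measured ecdysone response genes, 2 were higher in lgl and 12 did not pass, with 6 higher in lgl adjusted over the list alone. The ecdysone response list was higher in lgl (camera adjusted p = 0.0096, range 0.0045 to 0.42, adjusted p = 0.42 with an estimated correlation). Its members included Eip63E (0.99 ± 0.19). Among the 8 measured JAK/STAT genes, 1 was higher in lgl and 7 did not pass, with 2 higher in lgl adjusted over the list alone. The JAK/STAT list was higher in lgl (camera adjusted p = 0.032, range 0.014 to 0.29, adjusted p = 0.29 with an estimated correlation). The JAK/STAT call was also lost without scrib brain replicate 1 (adjusted p = 0.11). Its called member was chinmo (1.17 ± 0.34). The other 18 tested lists did not pass. The call of chinmo was lost with no filter (adjusted p = 0.12), without lgl brain replicate 1 (0.075), without lgl brain replicate 2 (0.12), without lgl brain replicate 3 (0.13), without scrib brain replicate 1 (0.14) and without scrib brain replicate 2 (0.13), range 0.017 to 0.14.

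The effect of each mutation with age was compared between tissues, as the change in discs minus that in brains. For lgl, limma called 1188 probe sets, 791 with the higher change in discs and 397 with the higher change in brains. That count was 171 with array weights by group, 706 in the fit on its arrays alone, 689 without the brain-enriched probe sets and 2437 without wild-type brain replicate 2. For scrib it called 996, 558 and 438, and 137 with array weights by group, 475 in the fit on its arrays alone and 2255 without wild-type brain replicate 2. The lgl effect was higher in discs for the glial list (camera adjusted p = 3.4e-05, adjusted p = 0.031 with an estimated correlation) and the neuronal list (1.3e-10 and 0.12). It was higher in brains for mitosis (0.00015 and 0.27), DNA replication (0.00079 and 0.3) and fat body markers (0.0069 and 0.37). The scrib effect was higher in discs for the neuronal list (2e-05 and 0.27), glycolysis (0.00015 and 0.27) and JNK genes (0.028 and 0.47). Only 2 of the 17 neuronal genes read 4 or more on both wild-type disc arrays, so this list had little room to fall in discs beside its fall in scrib brains. Higher in brains were DNA replication (2.7e-05 and 0.27), neuroblast markers (0.0048 and 0.3) and hemocyte markers (0.019 and 0.47). Of 25 lists, 10 passed for lgl and 11 for scrib with the preset correlation, and with an estimated one only the glial list passed, for lgl.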

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

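The 2 tests of the neural markers and the 2 tests of the fat body and muscle markers were chosen only after the result was seen, as was the separate test of chromosome arms in discs and in brains, unlike the splits of arrays and the test of the arms over either tissue.

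The effect of lgl differed between tissues for 1188 probe sets by a test of the difference itself, and for 171 with array weights by group, 706 in the fit on its arrays alone, 689 without the brain-enriched probe sets and 2437 without wild-type brain replicate 2. The change in discs minus the change in brains was 5.85 ± 0.71 SE for Capa (adjusted p = 0.00022), a neuropeptide gene, 5.63 ± 0.69 SE for Gad1 (adjusted p = 0.00024), 5.43 ± 1.03 SE for Cbp53E (adjusted p = 0.0045) and 5.41 ± 0.37 SE for Syn (adjusted p = 3.9e-06). Each rose in lgl discs and fell in lgl brains. Differences the other way were -9.59 ± 2.09 SE for Lsp2 (adjusted p = 0.0093), -9.09 ± 2.31 SE for Fbp2 (adjusted p = 0.021), -9.04 ± 1.92 SE for fon (adjusted p = 0.0081) and -8.85 ± 2.51 SE for Obp99b (adjusted p = 0.035), genes of fat body or blood. These fell in lgl discs and did not pass the test in lgl brains. The call of Fbp2 was lost with no filter (adjusted p = 0.073), with array weights by group (0.34), without wild-type disc replicate 1 (0.078) and without wild-type brain replicate 1 (0.06), range 0.01 to 0.34. The call of Obp99b was lost with no filter (adjusted p = 0.11), with array weights by group (0.45), in the fit on its arrays alone (0.064), without wild-type disc replicate 1 (0.099), without wild-type brain replicate 1 (0.11), without lgl disc replicate 2 (0.074), without lgl disc replicate 3 (0.065), without lgl brain replicate 1 (0.072) and without lgl brain replicate 3 (0.077), range 0.02 to 0.45. Weighting arrays by group ended the calls of Cbp53E (adjusted p range 0.00035 to 0.098), Lsp2 (0.0082 to 0.25) and fon (0.004 to 0.2).

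For scrib it differed for 996, and for 137 with array weights by group, 475 in the fit on its arrays alone and 2255 without wild-type brain replicate 2. Larger changes in discs were 6.87 ± 1.03 SE for Cyp6a20 (adjusted p = 0.0012), 5.08 ± 0.55 SE for bnl (adjusted p = 1e-04) and 5.04 ± 1.28 SE for Cpr64Ac (adjusted p = 0.024), which did not pass in brains, where bnl averaged 2.37 in wild type and 2.85 in scrib mutants. The difference was 4.88 ± 0.36 SE for NimA (adjusted p = 7.2e-06), a gene that fell by 4.88 in brains and averaged 2.75 in both disc groups. Lower changes in discs were -9.31 ± 2.31 SE for Fbp2 (adjusted p = 0.022), -8.14 ± 1.92 SE for fon (adjusted p = 0.017), -7.34 ± 2.09 SE for Lsp2 (adjusted p = 0.041) and -6.40 ± 0.90 SE for Spn100A (adjusted p = 0.00079). Spn100A averaged 2.34 in all 3 brain groups, near background, so its difference is the change in discs alone. The call of Cpr64Ac was lost with no filter (adjusted p = 0.078), with array weights by group (0.55), without wild-type disc replicate 2 (0.056), without wild-type brain replicate 1 (0.054), without scrib disc replicate 1 (0.053), without scrib disc replicate 3 (0.053) and without scrib brain replicate 3 (0.051), range 0.0054 to 0.55. The call of Fbp2 was lost with no filter (adjusted p = 0.073), with array weights by group (0.4), in the fit on its arrays alone (0.053), without wild-type disc replicate 1 (0.073), without wild-type brain replicate 1 (0.058) and without scrib disc replicate 2 (0.05), range 0.0088 to 0.4. The call of fon was lost with no filter (adjusted p = 0.059), with array weights by group (0.34) and without wild-type disc replicate 1 (0.059), range 0.0035 to 0.34. The call of Lsp2 was lost with no filter (adjusted p = 0.12), with array weights by group (0.49), in the fit on its arrays alone (0.072), without wild-type disc replicate 1 (0.12), without wild-type brain replicate 1 (0.1), without scrib disc replicate 1 (0.074), without scrib disc replicate 2 (0.072), without scrib disc replicate 3 (0.069), without scrib brain replicate 2 (0.06) and without scrib brain replicate 3 (0.067), range 0.019 to 0.49. Array weights by group ended the calls of bnl (adjusted p range 6.8e-05 to 0.055) and Spn100A (0.00014 to 0.093).

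For the difference between lgl and scrib mutants, the 6 arrays of a tissue make 10 splits into 3 and 3, too few for a share under 0.05. In discs the real split called 1805 probe sets and the highest other split 0, so 1 of the 10 gave as many (unadjusted p below 0.05 in the real split for 2948), and in brains it called 1014 and the highest other 13, again 1 of 10. The arms of l(2)gl (2L) and scrib (3R) come from the mutant stocks and may carry strain differences, though with 2 different alleles in trans the regions around these genes need not be homozygous, as the planned test had assumed. Over either tissue 27.4% of genes were called on these arms and 25.0% on X, 2R and 3L. Chromosome 4, with 59 genes, 44.1% called in discs and 18.6% in brains, was not counted. The ratio was 1.1 (interval 1.01 to 1.18, 2-sided Fisher exact p = 0.024), below the planned bound of 1.2. In discs alone it was 1.03 (0.94 to 1.13, Fisher exact p = 0.53). In brains it was 1.26 (1.11 to 1.44, Fisher exact p = 0.00063), between the bounds of 1.2 and 1.5. A ratio below 1.2 argues only against differences mainly on these arms, since 2R and 3L share their chromosomes. Strain differences elsewhere and the mutations stay open, as do these arms for brains.

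For the neural markers on the lgl disc arrays, brain tissue in the lgl disc samples may be a source. Of 26 abundant brain-specific genes, 88.5% were higher on all 3 lgl than on all 3 scrib disc arrays, at a median of 6.33%, 14% and 6.13% of their brain level. A first selection of 84 genes gave 92.9% and was replaced because it was not independent of the arrays compared, and the neuroblast markers reached only 0.779% of their brain level on lgl disc replicate 3, where the neuronal ones reached 8.11%. A lower share of disc epithelium alone stays open, since the fat body and muscle markers changed by 0.18 log2 beside 1.44 for the neuronal markers and the interval of the difference was -3.51 to 0.02. A first rule, on separate intervals, had excluded it, and neural gene activity in lgl disc cells was not tested.

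For the lower fat body and muscle markers in both mutant discs, uneven RNA of these tissues in the wild-type samples may contribute, since wild-type disc replicate 1 exceeded replicate 2 by a median of 2.52 log2 over 17 markers, at percentile 100 of 10000 random lists matched on mean level. Against replicate 2 alone the markers changed by -0.78 in lgl (interval -3.33 to -0.37) and -1.54 in scrib discs (-2.80 to -0.87). These intervals, and that for the neural markers above, resample markers and leave out the spread between samples. Both values lie below the bound of -0.5 written for replicate 1 not being the sole source, but the lgl interval crosses it and a single array remains, so this stays open. Age, which differs between wild type and mutants, was not tested.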

How the results depend on the processing

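Array weights by group, chosen after seeing the data as was the leaving out of brain-enriched probe sets, moved all 9 counts of probe sets and both overlaps by more than 1.5 times. They gave 829 probe sets for lgl discs, 880 for scrib discs, 254 for lgl brains and 780 for scrib brains against wild type. They gave 3529 for lgl against scrib discs, 1923 for lgl against scrib brains, 1844 for wild-type disc against brain, 171 and 137 for the lgl and scrib effects between tissues, and overlaps of 371 in discs and 179 in brains. These weights fell as the SD within groups rose, at 0.36 and 0.21 for wild-type discs and brains against 1.09 to 2.16 for mutants. The main fit pools the spread, which may favour calls against wild type. A fold of at least 2 as well left 1120 for scrib discs, 1135 for lgl brains, 1673 for scrib brains, 933 and 582 for lgl against scrib discs and brains, and overlaps of 489 and 758. A fit on the arrays compared gave 1363 for lgl brains, 583 for lgl against scrib brains, 1426 for wild-type disc against brain, 706 and 475 for the effects between tissues and 992 for the brain overlap, with fewer residual degrees of freedom. Without the brain-enriched probe sets, 689 were called for the lgl effect between tissues.

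Leaving out 1 array at a time gave 1204 to 3769 for lgl brains, 1050 to 1440 for lgl against scrib discs, 604 to 774 for lgl against scrib brains, 887 to 2437 and 730 to 2255 for the lgl and scrib effects between tissues, 913 to 2888 for the brain overlap and 5 to 9 gene lists for scrib brains. The cause was not tested. With an estimated correlation camera called 0 lists in each of the 6 comparisons, with unadjusted p below 0.05 for 4, 1, 3, 5, 6 and 3 lists. Of 477 named gene comparisons, 307 kept their call in every fit without 1 array, no direction reversed, and array weights ended 178, no filter 85, the fit on the arrays compared 73 and quantile normalization 18. Leaving out both replicate 1 wild-type arrays, chosen after seeing the data, ended 60 calls against wild type and left 287. The replicate numbers showed no general pairing of the mutant arrays. Of 36 pairs of arrays with the same number, 6 correlated above 0.1 (range -0.17 to 0.43), and 3 of 18 among mutant arrays (-0.11 to 0.23). Of 12 mutant arrays, 6 correlated best with their own number, and the share from chance alone was not computed. The 0.43 is that of wild-type discs and brains, whose replicates 1 and 2 had medians of 9.00 and 10.26 in discs and 7.52 and 8.87 in brains for ecdysone response genes, and 8.05 and 9.18, and 6.72 and 8.09, for JNK pathway genes. With a replicate block the 9 counts were 1589, 1887, 2160, 3024, 1774, 994, 3785, 1131 and 975, and 20 of the 477 calls ended. Of the called lists it ended only that of basement membrane genes in lgl brains (adjusted p = 0.06, range 0.012 to 0.46 over the alternatives). Signal near the floor limits what can be read, since 34.7% to 40.4% of the probe sets of an array lay at it.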

Other observations

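The genes in this part were chosen after their values were seen. Some differed by genotype in both tissues alike. The zinc transporter gene Zip102B averaged 10.25 log2 in scrib discs and 10.15 in scrib brains, and 3.83, 3.62, 3.66 and 3.67 in lgl discs, lgl brains, wild-type discs and wild-type brains. Hsc70-2, which encodes a heat shock cognate, averaged 2.51 in lgl discs and 2.21 in lgl brains, against 8.72 and 8.96 in the scrib groups.

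The 18S ribosomal control ranged from 6.74 to 10.25 log2 over the 16 arrays.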
